A study of Cereibacter sphaeroides 2.4.1 with 3 samples.

How the data were processed

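The data are 3 single-colour Affymetrix arrays of R. sphaeroides, 1 for each of 3 independent cultures of a PrrA- PpsR- strain, per the labels. RNA extraction and labelling are described in the labels only by reference to earlier work and to the manufacturer's protocol. The authors deposited 1 linear signal intensity per probe set and array, and the submitters' processing notes name MAS5, the Affymetrix algorithm that summarises perfect-match and mismatch probes; its version, the detection calls and the scanner values were not used here. The deposited intensities have no value at or below 0, and their mean without the lowest and highest 2% is 500.2 in cultures 1 and 2 and 500.1 in culture 3. A common scaling target near 500 is read from these values; it is not given in the sources used here. Such scaling makes arrays comparable in their trimmed mean, not in their median, and the 100 brightest probe sets carry 49.9%, 47.5% and 45.5% of the summed signal in cultures 1, 2 and 3. No column belonged to a sample of another series. At most 0.187% of values were identical between any 2 arrays, so no array was a copy of another. Array data have no read depth; the precision of each value is set by the 3 cultures and is worse for dim probe sets.

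Probe sets are numbered in the deposited table, and 542 of 5355 were paired with 1 gene symbol each in a table of the platform's annotation dated 2016, none with several; 4813 had no name in it. The 3 probe sets named thrC that carry the accession of the Affymetrix thr control were, from general knowledge of that accession and not from the labels, treated as spike-in controls and left out of all gene results. The other 539 probe sets belong to 514 genes by Entrez number, 10 of which have more than 1 probe set. The value of such a gene is the mean of its log2 signals, and its probe sets disagreed by 4.01 (log2) for ppsR, 3.21 for fliM and 2.53 for flhB between the highest and the lowest. Of these genes, 510 had a symbol that the reference gene table of assembly ASM332471v1 also holds; the build behind the array is not given in the sources used here, so that table served only to find neighbouring genes and no coordinates are printed. It has no strand, so the planned split of neighbours by strand was not made. The tables give no product names, so gene lists were matched by symbol alone and the planned comparison of both ways to match had nothing to compare. Of the named genes, 394 lay above the median of all probe sets; gene and intergenic probe sets without a name could not be told apart, so places among named genes and among all probe sets answer different questions.

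The series holds 1 group, so no difference between conditions was tested and no p-value is given. Before the data were examined, 22 gene lists, the named-gene rule and the alternatives were fixed. The rule names prrA and ppsR, the 2 brightest and 2 dimmest members of each list (4 and 4 for the photosynthesis and DMSO lists), the 10 brightest genes, and the 10 genes with the largest fold between cultures among those brighter than the median, read as a mean log2 signal above that of the median gene; genes named outside it (glpD, which a linear mean would have let in, fliM, flhB, fnrL, prrB and appA) were chosen after their values were seen, as were those of the closing part's groups, cycA and hfq. Of the lists, 20 had a measured member; those for nitrate, nitrite and nitric oxide reduction and for transposases and phage had none. For 15 lists with at least 4 members, the median percentile among named genes, the median SD between cultures and the median shift of each culture against the mean of the others were placed among 10000 random lists of the same size drawn from the named genes. For SD and shift the lists were matched in 20 bins of mean signal, and log2 signals were first centred on each array's median over all probe sets. A place outside 2.5 to 97.5 was read as standing apart; it describes these arrays and is not a p-value. Because the random lists are drawn from the same 514 genes, a large list such as the 45 ribosomal protein genes is partly compared with itself. For SD and shift the same holds for the photosystem genes, several of which share the brightest bin. Signals are given as deposited, as mean ± SD over the 3 cultures.

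Neighbour correlations used the deviations of 443 genes with a unique symbol in both tables, against 1000 permutations within the 20 bins. Alternatives were leaving out each culture, adding 17.3 (the 10th percentile of all signals) before log2, quantile normalization, no centring, a filter at the 25th percentile of mean signal, means for medians, 5 bins, ranges for SDs and percentiles among all probe sets; random lists from all probe sets, agreement over all probe sets, the brightest probe set per gene, quantile-normalized signals of single genes, neighbours without ribosomal protein genes, genes 10 places apart, and the other combinations of these neighbour settings were added after seeing the data. For a result inside the middle 95% under both settings, a turn of direction was counted as a move only where the value changed by over 1 SD of the random lists. The list statistics were tested on simulated arrays of 514 genes with 3 cultures. Lists of 10 genes shifted by 1 (log2) in 1 culture were placed above 97.5 in 100% of 200 cases, and lists with a 2-fold larger SD in 88.0%. Unchanged lists fell outside the middle 95% in 2.00% of cases for shift and 6.75% for spread. Smaller lists, smaller shifts, array-wide differences and lists crowded in the brightest bins were not simulated. The rates above therefore do not give the power of the list statistics on these arrays. Simulated neighbours that shared deviations equally at every signal level, without array-wide differences, were found in 100% of 10 sets and unrelated ones in 10.0%. Sharing that depends on signal was not simulated, so these rates do not give the power of the neighbour test on these arrays. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1; figures were drawn with matplotlib 3.10.9.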

Results

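Transcript levels were measured on 3 Affymetrix arrays, each hybridised with biotin-labelled cDNA made from the total RNA of 1 of 3 independent cultures of Rhodobacter (now Cereibacter) sphaeroides, a purple bacterium that can respire or photosynthesise. All 3 cultures belonged to 1 group. The strain is labelled as lacking both PrrA, the response regulator that activates photosynthesis genes when oxygen falls, and PpsR, a repressor of the same genes. The cells grew in the dark without oxygen under 95% N2 and 5% CO2, with 0.5% DMSO as electron acceptor and 0.1% yeast extract in the medium. The series title places the arrays in a study of the PpsR regulon. No other strain or condition was analysed here, so the values below are levels in this strain and no gene can be said to have risen or fallen because of either mutation. Each array gave a signal for 5355 probe sets. The median signal was 166.6 in culture 1, 163.6 in culture 2 and 181.0 in culture 3. Only 542 probe sets carried a gene symbol, 3 of them taken as a spike-in control, which left 514 named genes. Probe sets differ in how well they bind their target, so a percentile places a signal on the scale of these arrays and does not compare amounts of different transcripts. Percentiles of single genes below are among the mean log2 signals of all 5355 probe sets, and precision is limited by the number of arrays.

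The gene for PpsR gave weak and irregular signals. Its 5 probe sets had mean signals of 9.10 to 147, with single readings from 5.1 to 269.7. Averaged over the probe sets, ppsR stood at 55.4 ± 21.8 (SD, n = 3), at percentile 22.0. The 5 probe sets of fnrL, the gene for an anaerobic activator, stayed within 778.4 to 1092.1 on all arrays. That gene was far brighter, however, and bright probe sets varied less. The part of ppsR missing from the strain is not given in the sources used here, so these signals do not by themselves check the label. No probe set was paired with the symbol prrA in the tables used here, and its level is not reported. Among the other regulators, tspO, which encodes an outer membrane protein that modulates photosynthesis gene expression, had a signal of 1480 ± 77.6 (SD, n = 3). The signal of ppaA was 1170 ± 158, that of fnrL 902 ± 105 and that of prrB, the sensor kinase partner of PrrA, 614 ± 8.08. The signal of appA, whose product counteracts PpsR, was 89.3 ± 5.67, at percentile 32.9. Its 5 probe sets ranged from 61.6 to 123 in mean signal and from 51.5 to 175.6 in single readings. Between its highest and lowest probe set the mean log2 signals differed by 0.95, against 4.01 for ppsR. The transcription factor gene nifA had 86.7 ± 26.1. Of the 8 regulators measured, 4 lay above the median of all probe sets and 4 below it. The list's median percentile was 37.9 ± 1.57 among named genes, above 22.3% of random lists, and 61.2 among all probe sets, above 75.9% of random lists there.

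Most measured genes of the photosynthetic apparatus were among the brightest named genes on the arrays. Of the 17 symbols in this list, 7 had a named probe set. None was named for pufB or for the peripheral antenna genes pucA and pucB, so their levels are not reported. The signal of pufA, which encodes a light-harvesting polypeptide, was the highest of all named genes at 36544 ± 2825 (SD, n = 3). Within this list the reaction centre genes pufL and pufM followed with 23482 ± 2444 and 21634 ± 1714. The signals were 14492 ± 2135 for pufX, 13188 ± 1002 for the reaction centre gene puhA, and 8144 ± 514 for pufQ. The lowest of the 7 measured genes of this list was pucC, which is needed to assemble the peripheral antenna, with 1096 ± 74.4 at percentile 87.7. In all 3 cultures 6 of the 7 genes lay at or above the 75th percentile of the named genes. The list's median percentile among named genes was 97.2 ± 0.112 (SD over the 3 arrays), and its place was above 100% of 10000 random lists of the same size drawn from the named genes.

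**Figure D1:**
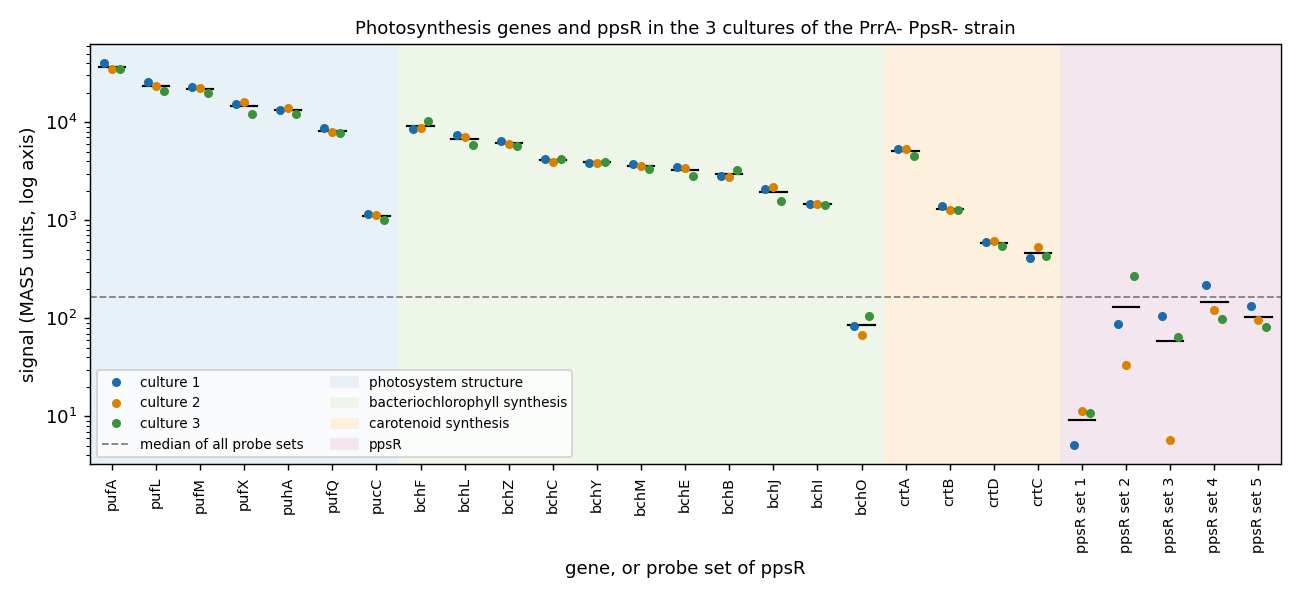
Signals of the measured photosystem, bacteriochlorophyll and carotenoid genes and of the 5 probe sets of ppsR (horizontal axis) on a logarithmic scale in MAS5 units (vertical axis). Points are the 3 cultures, short lines their means, and the dashed line the median of all probe sets at 166. The culture points of pufA to bchI lie close together. Those of ppsR run from 5.1 to 269.7 over all 5 probe sets and cultures, and the means of its probe sets from 9.1 to 147.

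Bacteriochlorophyll genes were bright too, with 1 exception. Of 11 measured bch genes, 10 lay above the 90th percentile of all probe sets. The highest signals were 9151 ± 1029 (SD, n = 3) for bchF, a hydratase gene, 6762 ± 760 for bchL, 6073 ± 387 for bchZ and 4128 ± 182 for bchC. Lower signals were those of bchB with 2947 ± 242, bchJ with 1963 ± 328 and bchI, a magnesium chelatase subunit gene, with 1455 ± 17.4. The exception was bchO, at 85.5 ± 18.9 and percentile 31.2. The list's median percentile among named genes was 84.1 ± 0.225, above 99.6% of the random lists. All 4 measured carotenoid genes lay above the median of all probe sets. The signal of crtA was 5055 ± 451, that of the phytoene synthase gene crtB 1317 ± 57.6, that of crtD 588 ± 31.0 and that of crtC 463 ± 67.8. The median percentile of these 4 genes was 65.4 ± 1.53 among named genes, above 79.3% of random lists, and 85.1 among all probe sets, above 98.2% of random lists drawn there.

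Of the genes for heme and the early tetrapyrrole pathway, 7 of 8 lay above the median of all probe sets. The oxygen-independent coproporphyrinogen oxidase gene hemN had 3075 ± 396 (SD, n = 3). Its oxygen-dependent counterpart hemF had 496 ± 47.1. The 2 genes for 5-aminolevulinate synthase gave 2395 ± 287 for hemA and 19.7 ± 13.1 for hemT, the latter at percentile 8.21. The median percentile of the list among named genes was 59.8 ± 2.54, above 73.6% of random lists, and 82.0 among all probe sets, above 98.8% of random lists there.

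Genes of energy metabolism included several with bright signals. The 3 measured genes of the cbb3-type oxidase, the terminal oxidase with high oxygen affinity, had 15777 ± 1086 (SD, n = 3) for ccoN, 16680 ± 2478 for ccoO and 11447 ± 1346 for ccoP. With 3 members, this list was not set against random lists. All 9 genes of NADH dehydrogenase lay above the median of all probe sets, from 1006 ± 134 for nuoN and 1297 ± 139 for nuoE to 3865 ± 310 for nuoI and 4808 ± 147 for nuoC. Their median percentile of 77.5 ± 0.225 among named genes was above 97.1% of random lists, just inside the middle 95%, and among all probe sets it was above 99.9%. The citric acid cycle list had a median percentile of 88.9 ± 0.419, above 99.9% of random lists, with 18941 ± 2982 for sucC and 10954 ± 1997 for sucD, the succinyl-CoA synthetase genes. Its lowest members were the second sdhA entry, with 170 ± 46.6, and the second fumC entry, with 47.4 ± 18.3. ATP synthase genes were listed as 2 pairs, with 8273 ± 379 for atpA and 5786 ± 65.3 for atpD in one, and 191 ± 28.3 and 238 ± 35.4 in the other. Their median percentile of 59.0 ± 1.45 among named genes was above 67.5% of random lists. Whether probe sets of such copies take up each other's transcripts is uncertain.

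The DMSO respiration list had 2 measured genes, both regulatory. The sensor kinase gene dorS gave 608 ± 106 (SD, n = 3) and the response regulator gene dorR 238 ± 43.4. Molybdopterin, the cofactor of DMSO reductase, requires MoaA, and 2 genes carried the symbol moaA. One gave 6522 ± 207, at percentile 97.4, and the other 457 ± 28.0, at percentile 75.5. The lowest of the 8 genes for the cofactor and for molybdate transport were modD with 83.9 ± 24.8 and modC with 32.4 ± 10.8. The median percentile of this list among named genes was 34.3 ± 0.913, above 15.3% of random lists, and 63.0 among all probe sets, above 80.2% of random lists there.

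Nitrogen fixation and motility genes were dim. All 11 measured nitrogen fixation genes lay below the median of all probe sets and at or below the 25th percentile of named genes in every culture. The nitrogenase iron protein gene nifH had 64.7 ± 18.9 (SD, n = 3), nifD 10.7 ± 3.18 and nifW 7.0 ± 1.97. The list's median percentile among named genes was 5.16 ± 1.18, above 0% of random lists. All 20 flagellar and motility genes lay below the median of all probe sets, from 144 ± 31.9 for flgB and 139 ± 28.5 for flgA to 10.5 ± 6.67 for flgH and 7.90 ± 5.01 for fliQ. This holds for fliM only as the mean of 2 probe sets, with mean signals of 233 and 27.6. Their median percentile of 5.35 ± 1.73 was also above 0% of random lists. The 5 hydrogenase maturation genes ranged from 51.8 ± 10.8 for hypA and 73.9 ± 23.0 for hypE to 132 ± 43.5 for hypF and 177 ± 36.9 for hypB. Their median percentile of 17.6 ± 1.54 was above 4.12% of random lists, inside the middle 95%. Their mean percentile of 16.2 was above 0.29%, whereas among all probe sets their median percentile of 41.5 was above 34.5% of random lists there. The gas vesicle genes gvpA and gvpJ had 92.9 ± 35.8 and 47.5 ± 32.8. Single genes stood for CO2 fixation, cbbX with 124 ± 7.16, and for polyhydroxyalkanoate synthesis, phaC with 172 ± 14.0. Detection calls were not used here, so a dim signal is not shown to be above or below background.

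**Figure D2:**
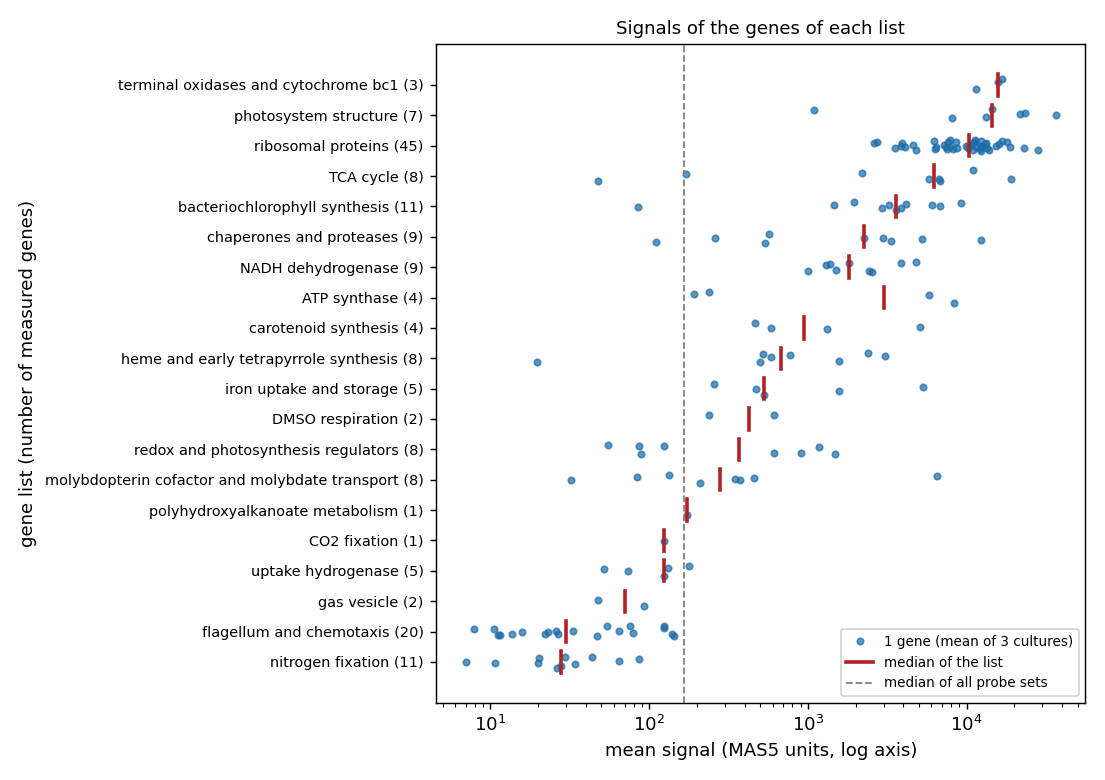
Mean signal over 3 cultures of each measured gene (horizontal axis, logarithmic, MAS5 units) by gene list (vertical axis, number of genes in brackets). Red bars are list medians and the dashed line is the median of all probe sets at 166; all 11 nitrogen fixation genes and all 20 flagellar genes lie left of it, and all 45 ribosomal protein genes lie right of it.

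Genes for protein synthesis and folding were bright. All 45 ribosomal protein genes lay at or above the 75th percentile of named genes in every culture, from 2611 ± 259 (SD, n = 3) for rpmB and 2743 ± 256 for rpsP to 22847 ± 3138 for rpsL and 28158 ± 2528 for rplJ. The list's median percentile of 93.3 was above 100% of random lists. Of the 10 brightest named genes, 5 encode ribosomal proteins, with rplL at 18767 ± 1487, rplB at 17900 ± 1927 and rpsC at 16757 ± 1769 beside rplJ and rpsL. Among 9 chaperone and protease genes, 1 groEL entry had 12373 ± 436 and the membrane protease gene ftsH 5249 ± 436, while clpB had 261 ± 43.1 and the other groEL entry 110 ± 40.0. This list's median percentile of 79.5 ± 0.405 was above 97.9% of random lists, above 95.0% when only genes above the 25th percentile of signal were used, and above 94.5% as a mean over members. The 5 iron genes lay above the median of all probe sets, with 5290 ± 418 and 1574 ± 144 for the 2 bacterioferritin genes named bfr, 470 ± 83.6 for exbD and 256 ± 10.9 for exbB. Their median percentile of 54.4 ± 1.62 was above 58.2% of random lists.

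The 3 cultures were compared to see how far single genes varied without any change of strain or medium. Across the 514 named genes, Pearson's r of log2 signals was 0.981 between cultures 1 and 2, 0.982 between 1 and 3 and 0.978 between 2 and 3, with Spearman's rho of 0.987, 0.988 and 0.985. These are correlations across genes, which are not independent replicates. The median SD between cultures was 0.18 on the log2 scale for named genes and 0.26 for all probe sets. The spread depended on the signal. The median SD was 0.79 in the dimmest 25% of all probe sets and 0.15 in the brightest 25%, and the highest and lowest cultures differed over 2-fold for 70.7% of probe sets in the former and 1.49% in the latter. The widest range of all named genes was that of glpD, the glycerol 3-phosphate dehydrogenase gene, with 154.5, 1248.2 and 134.9 in cultures 1, 2 and 3, a 10.2-fold range after centring each array on its median. Among named genes with a mean log2 signal above the median, which leaves out glpD, ugpB, whose product binds glycerol 3-phosphate, varied most. Its signal was 420.9, 911.3 and 354.9 in cultures 1, 2 and 3, a 2.84-fold range after the same centring, which also underlies the ranges below. The next was xdhA, with a 1.78-fold range and its lowest signal in culture 3. Of the 8 that followed, 5 encode ribosomal proteins (rplN, rpmC, rplE, rpsH and rpsS), with ranges of 1.56-fold to 1.67-fold and the lowest signal in culture 3, and the others were InfC, secY and rimM.

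The median SD of each of 15 lists with 4 or more members lay within the middle 95% of random lists matched on mean signal. It was 0.19 for the photosystem genes, 0.15 for bacteriochlorophyll genes, 0.22 for ribosomal protein genes and 0.29 for citric acid cycle genes, the last above 96.4% of matched lists. Without 1 culture each these values ranged from 0.07 to 0.23, 0.03 to 0.17, 0.05 to 0.27 and 0.06 to 0.36. Without culture 1 the ribosomal protein and citric acid cycle genes, and without culture 3 the bacteriochlorophyll genes, lay outside the middle 95% of matched lists. Lists also lay outside it under other settings: ribosomal protein and citric acid cycle genes with 5 bins (above 99.6% and 98.2%), NADH dehydrogenase genes after quantile normalization (above 2.48%), and ribosomal protein genes and regulators against all probe sets (above 98.7% and 2.28%). Of 45 shifts of a list in 1 culture against the other 2, 1 lay outside the middle 95%, where chance gives 2.25. It was the flagellar list in culture 3, at -0.23 on the log2 scale. Without culture 1 this shift was -0.12 and without culture 2 it was 0.01, both inside the middle 95%. After centring on the median of each array, ribosomal protein genes were shifted by -0.36 in culture 3 and photosystem genes by -0.32, above 11.3% and 86.8% of matched random lists. The ribosomal shift lay outside the middle 95% without culture 1, as a mean over members and against all probe sets. Quantile normalization brought the ribosomal and photosystem shifts to -0.04 and 0.01, but it removes the shift of any gene that keeps its rank, whatever the cause. Part of each shift in culture 3 came from the centring, since that culture had the highest median signal. With 1 culture against 2, these shifts have no replicate check.

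Genes next to each other on the chromosome are often transcribed together, so the deviations of neighbours from their means over the 3 cultures were compared. Over 142 pairs of adjacent named genes, whose strand was not used, the correlation of deviations was 0.05. Permuting gene positions within bins of signal gave a mean of 0.10, and the observed value was above 29.0% of permutations. With genes above the 25th percentile of signal, 101 pairs gave 0.58, above every one of 1000 permutations, which reached 0.55 at most and averaged 0.37. Leaving out ribosomal protein genes as well, an alternative chosen after seeing the data, 66 pairs gave 0.36, above 98.7% of permutations. Genes 10 places apart, also chosen after, gave 0.63 over 57 pairs with ribosomal protein genes, above 99.9% of permutations, and 0.30 over 34 pairs without them, above 91.6%. Quantile normalization over the 142 pairs gave -0.06, above 25.5% of permutations. Combined with the filter on signal, a choice made after seeing the data, it gave 0.21 for the 101 adjacent pairs, above 99.5%. For the 57 pairs 10 places apart it gave 0.13, above 89.8%. Without ribosomal protein genes the adjacent pairs then gave 0.19, above 97.7%, and those 10 places apart 0.08, above 73.6%. The difference between adjacent and distant pairs was not tested. In all, 36 combinations of normalization, signal range, ribosomal protein genes and distance were computed. Of these, 8 gave a correlation above the middle 95% of permutations, all with genes above the 25th percentile of signal, and 2 lay above every permutation. Among the dimmest genes, leaving out ribosomal protein genes changed no value, so those combinations repeat others.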

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

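Alternatives with random lists or agreement from all probe sets, the brightest probe set, quantile-normalized signals of single genes, and distance, ribosomal proteins and combined settings for neighbours were chosen after seeing the data. The others were planned. No paired analysis was possible because there is 1 group. Members by symbol alone and strand were not run, and lists left with under 4 members, or a culture's shift without that culture, gave no value. Of the alternatives for the 15 lists set against random lists, 92 of 102 for levels, 140 of 162 for spreads, and 309 of 351 for shifts kept their side of the middle 95% without a turn of direction beyond the spread of random lists, and 350 of 352 for signals of named genes stayed within 1 SD. By arithmetic alone, leaving out 1 culture could not move the signal of a named gene by 1 SD over the cultures. That part of the 352 therefore does not show that these signals are stable. For levels, leaving out 1 culture changed none of the 15 lists, so every change came from the other alternatives. For levels of the 5 smaller lists, given as values only, 21 of 32 stayed within 1 SD over arrays. The causes were not tested. Precision was lowest for dim genes, whose background was not measured: 70.7% of the dimmest 25% of probe sets differed over 2-fold between cultures. The ppsR signal was 48.8 to 68.0 without 1 culture each, 66.3 with the added constant and 147 for its brightest probe set; its percentile of 9.05 among named genes became 22.0 among all probe sets.

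Median percentiles lost their place outside the middle 95% for chaperones with the filter on dim genes (74.4) and as a mean (65.2). They gained one among all probe sets for carotenoid (85.1), heme (82.0) and NADH dehydrogenase genes (91.9), and as a mean for NADH dehydrogenase (77.7) and hydrogenase genes (16.2), the latter at 41.5 among all probe sets, well inside. They crossed the middle for regulators with the filter (57.4) and among all probe sets (61.2), and for molybdopterin genes among all probe sets (63.0).

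Without 1 culture each, spreads (log2) ranged from 0.047 to 0.265 for ribosomal proteins, 0.366 to 0.442 for flagellar, 0.0604 to 0.356 for citric acid cycle, 0.053 to 0.156 for iron, 0.0726 to 0.225 for photosystem, 0.0294 to 0.169 for bacteriochlorophyll, 0.0502 to 0.239 for carotenoid and 0.184 to 0.409 for hydrogenase genes; ribosomal and citric acid cycle genes lay outside the middle 95% without culture 1, and bacteriochlorophyll genes without culture 3. Quantile normalization gave 0.091 for carotenoid, 0.0756 for ribosomal and 0.0608 for NADH dehydrogenase genes, the last now outside. No centring gave 0.105 for carotenoid and 0.112 for iron genes, and the range in place of the SD 0.307 for iron genes. With 5 bins, ribosomal (0.216) and citric acid cycle genes (0.286) lay outside. Against all probe sets, ribosomal genes (0.216) and regulators (0.122) did, and the brightest probe set gave 0.225 for regulators.

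The shift of flagellar genes in culture 3 lost its place against all probe sets (-0.228) and ranged from -0.116 to 0.00834 without 1 culture each, a reversal without culture 2 and a place inside the middle 95% without culture 1. Under the same leaving out, ribosomal shifts ranged from -0.0123 to 0.375 in culture 2 and -0.375 to -0.345 in culture 3, both outside the middle 95% without culture 1; nitrogen fixation from -0.150 to 0.0918 in culture 1, -0.0918 to 0.847 in culture 2 and -0.847 to 0.150 in culture 3. The ranges in culture 2 were -0.00445 to 0.319 for photosystem, -0.00301 to 0.178 for bacteriochlorophyll, -0.208 to 0.242 for hydrogenase and -0.0692 to 0.202 for citric acid cycle genes, and in culture 1 -0.133 to 0.0416 for iron, -0.0529 to 0.230 for carotenoid, -0.0652 to 0.065 for NADH dehydrogenase and -0.144 to 0.0633 for chaperone genes. Quantile normalization turned photosystem shifts to -0.0231, -0.0352 and 0.0127 in cultures 1, 2 and 3, bacteriochlorophyll to -0.0117 and 0.0147 in 2 and 3, citric acid cycle to -0.00985 and 0.00913 in 2 and 3, NADH dehydrogenase to -0.0542 and 0.0831 in 1 and 3, and in culture 3 heme to 0.00638, chaperones to 0.0821 and iron to 0.0828. No centring turned culture 3 to 0.0432 for heme, 0.0453 for NADH dehydrogenase, 0.0842 for chaperones and 0.0993 for iron. The filter put heme in culture 3 outside (0.0875). Means gave 0.103 for heme in culture 1, -0.121 for regulators in culture 2, -0.268 for nitrogen fixation in culture 3, 0.056 for flagellar in culture 1, -0.0737 for citric acid cycle in culture 2 and -0.377 for ribosomal genes in culture 3, the last outside. Against all probe sets, ribosomal genes lay outside in cultures 2 (0.207) and 3 (-0.363).

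Agreement between cultures 1 and 2, 1 and 3, and 2 and 3 was Pearson's r 0.988, 0.988 and 0.984 with the added constant, 0.990, 0.991 and 0.987 with the filter (rho 0.979, 0.982 and 0.976) and 0.949, 0.939 and 0.945 over all probe sets (rho 0.960, 0.952 and 0.957). Genes over 2-fold numbered 52, 34 with the constant, 3 with the filter, 28 to 34 without 1 culture each, where the median SD was 0.110 to 0.177, and 1342 of all probe sets. The neighbour correlation of 0.05 became 0.58 with the filter and 0.36 also without ribosomal proteins.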

Other observations

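The gene groups in this part and the tests on the spike-in control, the photosystem genes in culture 3, the ppsR probe sets, the dimmest genes and genes 10 places apart or without ribosomal protein genes were chosen after the data were seen. The neighbour test over all named genes, its filter on dim genes and quantile normalization were planned, each singly. The combination of filter and quantile normalization was added after the data were seen. The reading of the filtered value as a test of noise also came after it was seen. Genes outside the fixed lists were grouped by the first 3 letters of their symbols, which gave 13 groups of 5 or more genes. Histidine utilisation genes were the dimmest of these groups: all 5 hut genes lay below the median of all probe sets, from 144 ± 14.0 (SD, n = 3) for 1 of 2 hutH entries to 13.7 ± 0.173 for hutU, the urocanase gene, with a median percentile of 13.3. Of all 514 named genes, 394 lay above that median. So did all 10 purine synthesis genes, from 337 ± 61.2 for PurD to 2088 ± 124 for purS, all 6 dap genes, all 5 sec genes and all 5 trp genes. Among named genes the median percentile was 62.0 for the purine group, 51.2 for dap, 73.4 for sec and 49.5 for trp. Of 10 cobalamin synthesis genes 9 lay above the median of all probe sets, the highest being cobS with 1232 ± 188, and cobD with 143 ± 22.8 below it, but their median percentile among named genes was 36.0. Among RNA polymerase genes, rpoZ, the omega subunit gene, had 5365 ± 435, rpoB 4155 ± 390 and rpoC 1530 ± 106. Of the sigma factor genes, rpoD had 1658.5 ± 179, rpoE 137.5 ± 13.8 and the 1 entry named rpoN 7.5 ± 2.19. The signal of cycA, which encodes cytochrome c2, was 14722 ± 724, and that of hfq, the gene for an RNA chaperone, 4709 ± 778. Of the 100 brightest probe sets, 56 had no name in the tables used here, as had 19 of the 20 among the brightest 25% that differed over 2-fold between cultures.

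Bright gene lists lay lower in culture 3 after centring on the median. The 3 thrC probe sets, taken as a spike-in control from their accession and not from the labels, shifted there by -0.31 (SD 0.0119 over probe sets), next to -0.32 for photosystem genes. The brightest 25% of all probe sets shifted by -0.13 and the dimmest 25% by 0.14, so the shift depended on signal. Centring itself lowered every value of culture 3, whose median of 181.0 was above the 166.6 and 163.6 of cultures 1 and 2. A change limited to the photosystem genes is argued against, since ribosomal protein genes shifted by -0.36 there. The photosystem shift was above 86.8% of random lists matched on signal, but that place says little. Several photosystem genes share the brightest bin with ribosomal protein genes, so the matched lists are partly made of both. A difference in signal scale between arrays, not the same at all signals, may account for the shift and stays open. The presumed control, whose spiked amounts are not given in the sources used here, fell just short of the shift it was set to reach. Quantile normalization moved the photosystem shift to 0.01, but it gives equal ranks equal values on every array. A gene that keeps its rank then loses its shift whatever the cause, so this value decides nothing. No biological explanation was tested, since all cultures belong to 1 group.

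The probe sets of ppsR differed between cultures, with a median SD of 0.65 (log2). Sets of 5 probe sets matched on signal had a median of 0.42, with 0.20 to 0.86 as their middle 95%, and the ppsR value was above 89.3% of them. The spread was larger than in most sets this dim but inside their middle 95%. The matched sets are not known to be background, because detection calls were not used. A weak transcript could give the same place, so background signal stays possible but was not told apart from one. Which part of the gene the strain lacks is not given in the sources used here, so a remaining transcript was not tested.

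Whether deviations between cultures are independent noise of single probe sets was tested through neighbouring genes. Over all named genes the correlation was 0.0452, and -0.06 after quantile normalization, both inside the permuted range. As planned, a value inside the permuted range was to be read as independent noise, and the value over all named genes met that. This reading was replaced only after the split by signal given below was seen. The value is now taken as unable to tell whether deviations are independent, because deviations were not scaled and dim genes weigh most. The median SD was 0.79 in the dimmest 25% of all probe sets and 0.15 in the brightest 25%. The -0.12 over 24 pairs of the dimmest 25% of named genes decides nothing. After a split by signal, independent noise is argued against for genes above the 25th percentile, with 0.58 above every permutation. That reading required a value above every permutation, which 2 of 36 settings gave. Quantile normalization of these genes left 0.21, above 99.5% of permutations. Without ribosomal protein genes, and without that normalization, the value was 0.36, above 98.7%. Both lay below the highest permuted values, 0.30 and 0.41, so neither meets that requirement. Genes 10 places apart gave 0.63, above 99.9%. They lay inside the middle 95% without ribosomal protein genes (0.30 over 34 pairs, above 91.6%) and after quantile normalization (0.13 over 57 pairs, above 89.8%). Adjacent genes stayed outside it in both settings, but with more pairs, 66 and 101. The difference between adjacent and distant pairs was not tested. Shared array-wide scale differences, which the permuted mean of 0.37 carries, and shared transcription may both contribute, and these were not separated.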
